A study of Homo sapiens with 2 samples.

How the data were processed

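The series holds 2 arrays of total RNA from MKN1, an established human gastric cancer cell line. One line was made to overexpress wild-type RHOA, and the other RHOA carrying the Y42C substitution, in each case from a retroviral plasmid with puromycin selection. Per the labels' protocols, RNA was purified on silica columns and turned into biotinylated cRNA for an Affymetrix array. There was 1 array per line, so each group has 1 sample, and no replicate error, standard error or p-value can be given for any difference.

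The deposited table gives 1 value per probe set and array for 21448 probe sets, with 2 decimals, between 2.23 and 18.16. These values were taken as log2 signal because of their range. The log base is not stated in the sources used here, so every fold below assumes that the deposited values are log2. Per the submitters' processing notes, the authors used Affymetrix Expression Console. Its version, the background correction, the summary method and the normalization between arrays are not given in the sources used here. The 2 columns had close but not identical distributions: their medians were 6.42 for wild-type and 6.36 for Y42C, and their sorted values differed by 0.0553 on average and by 0.15 at most. The values were used as deposited. Arrays give no read depth, and the number of arrays limits the precision.

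The platform annotation gave 1 gene symbol for 17709 probe sets, several for 0, and 3739 probe sets are unnamed here. All 17709 matched the gene table through their Entrez identifier, and 0 symbols changed. Probe sets of 1 gene were averaged, which concerned 20 of 17687 genes. The files name no genome build, so no coordinates are given. The gene table, on its own assembly, served only for the order and spacing of genes and for their genomic span.

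No probe set came with a detection call. A minimum was therefore set from 349 olfactory receptor genes, which a gastric line is not thought to use: a gene was kept when at least 1 array reached the 95th percentile of these genes on that array (5.17 for wild-type and 5.14 for Y42C). This kept 11802 genes, among them 22 olfactory receptor genes. Where the dimmer array lay below its minimum, the fold is given as a lower bound, the brighter value over the minimum of the dimmer array. Counts of genes past 2-fold use the deposited values, so they can include genes whose bound is under 2-fold.

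Differences are Y42C minus wild-type. Genes at least 2-fold apart were counted in each direction. For 36 gene lists the median difference of the members above the minimum was computed, with a bootstrap interval over members (2000 resamples, 95%). Its percentile was taken among the medians of 10000 random lists of the same size, drawn from the genes above the minimum and matched on mean level in 20 bins. The percentile and the interval describe these 2 arrays. They do not replace replicates, and random lists lack the co-variation of genes that share a function, so percentiles near 0 or 100 are common for real lists. Of 985 list entries, 885 were named here. The results of 34 of the 36 lists are reported. Lists, minimum, thresholds and naming rule were fixed before the data were examined. The rule names RHOA, RHOB and RHOC, the 12 most positive and 12 most negative differences, up to 2 members at each end of every list, every member of the 7 main lists past 2-fold, and 9 genes of lipid synthesis and chemokine signalling wherever they lay; further list members were named after their values were seen, to illustrate a count.

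The scripts were tested on simulated data for this comparison with 11802 genes and a simulated SD of 0.2. All 150 genes changed by 4-fold or 8-fold passed the 2-fold threshold, 0 of 50 genes changed by 1.5-fold did, and 0 unchanged genes did. Gene calls were not simulated at the larger SD of the data, so these counts check the code and give no error rate for the real calls. Of 200 unshifted lists of 25 genes, 7 lay outside the middle 95% of random lists. Of 50 lists shifted by 0.2, all 50 lay above percentile 97.5 at this SD, but 14 did at the SD of the data, 0.768, so a shift of that size was mostly not detectable here. The alternatives were centring, quantile normalization, removal of a trend on level (lowess, span 0.3), other expression minimums, other thresholds, a constant of 16 added to the linear value, the brightest probe set in place of the mean, and other summaries of a list. Values below the minimum set to it were added after the data were seen. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, statsmodels 0.14.6 and matplotlib 3.10.9 were used.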

Results

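Gene expression was measured on 1 array for each of 2 MKN1 lines, one overexpressing wild-type RHOA and the other RHOA Y42C. RHOA is a small GTPase that controls actin contractility through its effectors, and Y42C, a tyrosine-to-cysteine change, is a substitution found in gastric cancer. The comparison asks which transcripts differ between cells made to overexpress the mutant and cells made to overexpress the wild-type protein. The series holds no array of parental or empty-vector cells, so it cannot tell in which of the 2 lines a level changed. With 1 array per line there was no replicate, so the differences below carry no error between samples and no test, and they compare these 2 lines, not the 2 alleles in general.

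In the Y42C array, target genes of the actin-regulated SRF-MRTF and YAP-TAZ transcription factors were higher as lists, with 8 of 28 and 7 of 17 members at least 2-fold higher and 0 lower. FASN, the fatty acid synthase, was 7.06-fold higher, and the matrix gene FN1 6.92-fold. Interferon-gamma response genes were lower in 14 of 15 cases, with IRF1 4.06-fold lower, and DNA replication genes were lower in 30 of 35 cases. SPRR1A had the largest positive difference (135-fold) and SERPINB4 the largest negative one (20.5-fold lower).

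RHOA signal was high and close in both arrays, at 16.47 in the wild-type and 16.30 in the Y42C array on the log2 scale. Both lines carry a RHOA vector, and the probe set was not assumed to separate mutant from wild-type RNA, so this value does not check the labels. RHOC differed little (12.22 and 11.97). RHOB, which growth factors and stress induce, was 5.58-fold higher in the Y42C array (7.55 and 10.03).

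Across the 11802 genes above the minimum the 2 arrays correlated at r = 0.959 across genes, and genes are not independent replicates. At least 2-fold higher in the Y42C array were 881 genes (7.46%), and 1157 genes (9.80%) were at least 2-fold lower. Past 4-fold, 118 genes were higher and 69 lower. Past 8-fold, 19 were higher and 4 lower. The median difference was -0.07 and the SD 0.768. Olfactory receptor genes, which serve as a background set at low signal, had an SD of 0.440, and 4.30% of them passed 2-fold. In 20 bins of signal level the scaled median absolute deviation was lowest in the brightest bin (0.474) and highest in the dimmest (0.919). It did not rise steadily between them: the bin next to the dimmest had 0.556, and the highest value above the dimmest bin was 0.808. At least 2-fold apart and more than 3 times the spread of their bin from the median of genes of like level were 114 higher and 47 lower genes.

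**Figure D1:**
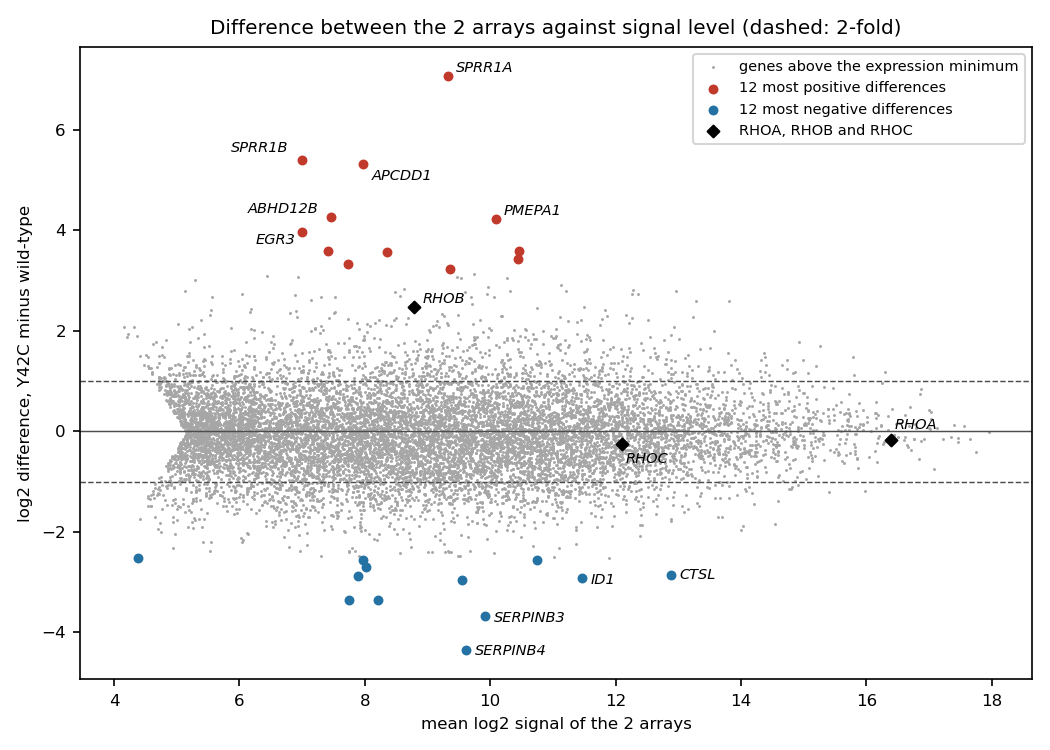
Each point is 1 of the 11802 genes above the expression minimum, with the mean log2 signal of the 2 arrays on the x axis and the log2 difference, Y42C minus wild-type, on the y axis; dashed lines mark 2-fold. SPRR1A (7.08) and SERPINB4 (-4.36) lie at the ends, RHOB is at 2.48, and RHOA (-0.17) and RHOC (-0.25) lie near 0.

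The 12 most positive differences included SPRR1A and SPRR1B, cornified envelope proteins of squamous epithelium. SPRR1A was 135-fold higher in the Y42C array (5.78 and 12.86). SPRR1B was at least 23.1-fold higher, its wild-type value of 4.30 being below the minimum, a bound that lies below the fold of APCDD1. These close relatives may share probes. APCDD1, a membrane inhibitor of Wnt signalling, was 40.2-fold higher, and ABHD12B 19.2-fold. PMEPA1, a TGF-beta target that limits SMAD signalling, was 18.8-fold higher, and EGR3, an immediate-early transcription factor, at least 14-fold. NTRK3, a neurotrophin receptor, AOC1, a diamine oxidase, and RASGRP1, a RAS exchange factor, differed by 3.60, 3.59 and 3.58 on the log2 scale. The list of 12 closed with the collagenase MMP1 (10.9-fold), the Notch coactivator MAML1 (10.1-fold) and the gelatinase MMP9 (9.38-fold).

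At the other end stood SERPINB4 and SERPINB3, the squamous cell carcinoma antigens, which were 20.5-fold and 12.8-fold lower in the Y42C array. They too are near-identical and may share probes. SLC12A8 was 10.3-fold lower, XPNPEP3, a mitochondrial aminopeptidase, 10.2-fold, and ASAP3, an ARF GTPase-activating protein, 7.73-fold. ID1, a BMP-responsive inhibitor of differentiation, was 7.57-fold lower, BLVRA, a biliverdin reductase, 7.31-fold, and the lysosomal protease CTSL 7.26-fold. TCP11L2 (6.54-fold), DPYD, which degrades pyrimidines (5.94-fold), and ZNF326 (5.90-fold) followed. NFE2 was at least 1.42-fold lower, since its Y42C value of 3.11 was below the minimum, and its place among these 12 rests on that value.

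Targets of the actin-regulated SRF-MRTF transcription factors were higher in the Y42C array as a list. Of 28 members above the minimum, 8 were at least 2-fold higher and 0 at least 2-fold lower. The 8 were FOSL1, an AP-1 subunit (6.68-fold), MICAL2, an actin oxidase (3.84-fold), SRF itself (3.53-fold), ITGA5 (3.10-fold), CCN2 (2.93-fold), ZYX (2.79-fold), TAGLN (2.69-fold) and MYH9 (2.53-fold). PDLIM7 and TGFB1I1 lay at the lower end (-0.60 and -0.54). The list's median was 0.50 (bootstrap interval 0.16 to 0.94), at percentile 100 of random lists.

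YAP-TAZ target genes, which respond to cell shape and tension, gave a similar count. Of 17 members, 7 were at least 2-fold higher and 0 lower, with a median of 0.81 (0.19 to 1.55) at percentile 100. PTPN14 (4.06-fold), ANKRD1 (3.92-fold), LATS2 (3.51-fold) and FJX1 (3.34-fold) were highest, followed by CCN2 (2.93-fold), ARHGEF17 (2.77-fold) and DOCK5 (2.73-fold). MYOF and NT5E lay at -0.78 and -0.36. CCN1 and CCN2 stand in this list and in the SRF-MRTF list, so the lists are not separate observations. Focal adhesion and integrin genes had 11 of 26 members at least 2-fold higher and 0 lower, with a median of 0.77 (0.36 to 1.26) at percentile 100. TNS4, a tensin, was 4.99-fold and the collagen receptor subunit ITGA2 3.68-fold higher, and ITGAV, ITGB3 and ITGB5 differed by 1.84, 1.76 and 1.26. LIMS1 and CAV2 lay at -0.76 and -0.43, and ITGA5, VCL and ZYX are also SRF-MRTF list members.

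Genes that act below RHOA had a smaller median shift. Of 24 RHOA effectors and actomyosin regulators, 20 were higher, 3 of them at least 2-fold higher, among them MYL6 (2.68-fold) and MYH9, and CFL2 was the 1 gene at least 2-fold lower (2.22-fold). PPP1CB, a catalytic subunit of myosin phosphatase, lay at -0.87. Their median of 0.20 lay within the middle 95% of random lists (percentile 93.6), and their mean of 0.30 outside it (97.9).

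Mesenchymal markers split into members that were much higher and members that were slightly lower. Of 20 members, 9 were at least 2-fold higher and 0 at least 2-fold lower. The matrix genes FN1 and COL5A1 were each 6.92-fold higher, TNC 6.36-fold, LUM 4.86-fold, COL6A1 3.36-fold, COL5A2 3.05-fold and COL1A2 2.06-fold. S100A4 was 5.31-fold and the transcription factor SNAI2 4.08-fold higher. ZEB1 (-0.92), TWIST1 (-0.86) and VIM (-0.72) were lower by less than 2-fold. The median was 0.59 (-0.26 to 1.89), at percentile 99.98, and 1.04 with the array median as minimum. Epithelial markers were not lower as a list: of 26, 4 were at least 2-fold higher and 2 lower. SPINT1 and ST14, a protease inhibitor and its target matriptase, were 6.96-fold and 4.76-fold higher, CLDN1 2.68-fold and OVOL2 2.57-fold. The protease PRSS8 was 3.97-fold and the tight junction gene CLDN7 2.46-fold lower. Their median was 0.26 (-0.12 to 0.57) at percentile 97.9, and at 96.7 once SPINT1, the member with the largest difference, was left out.

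**Figure D2:**
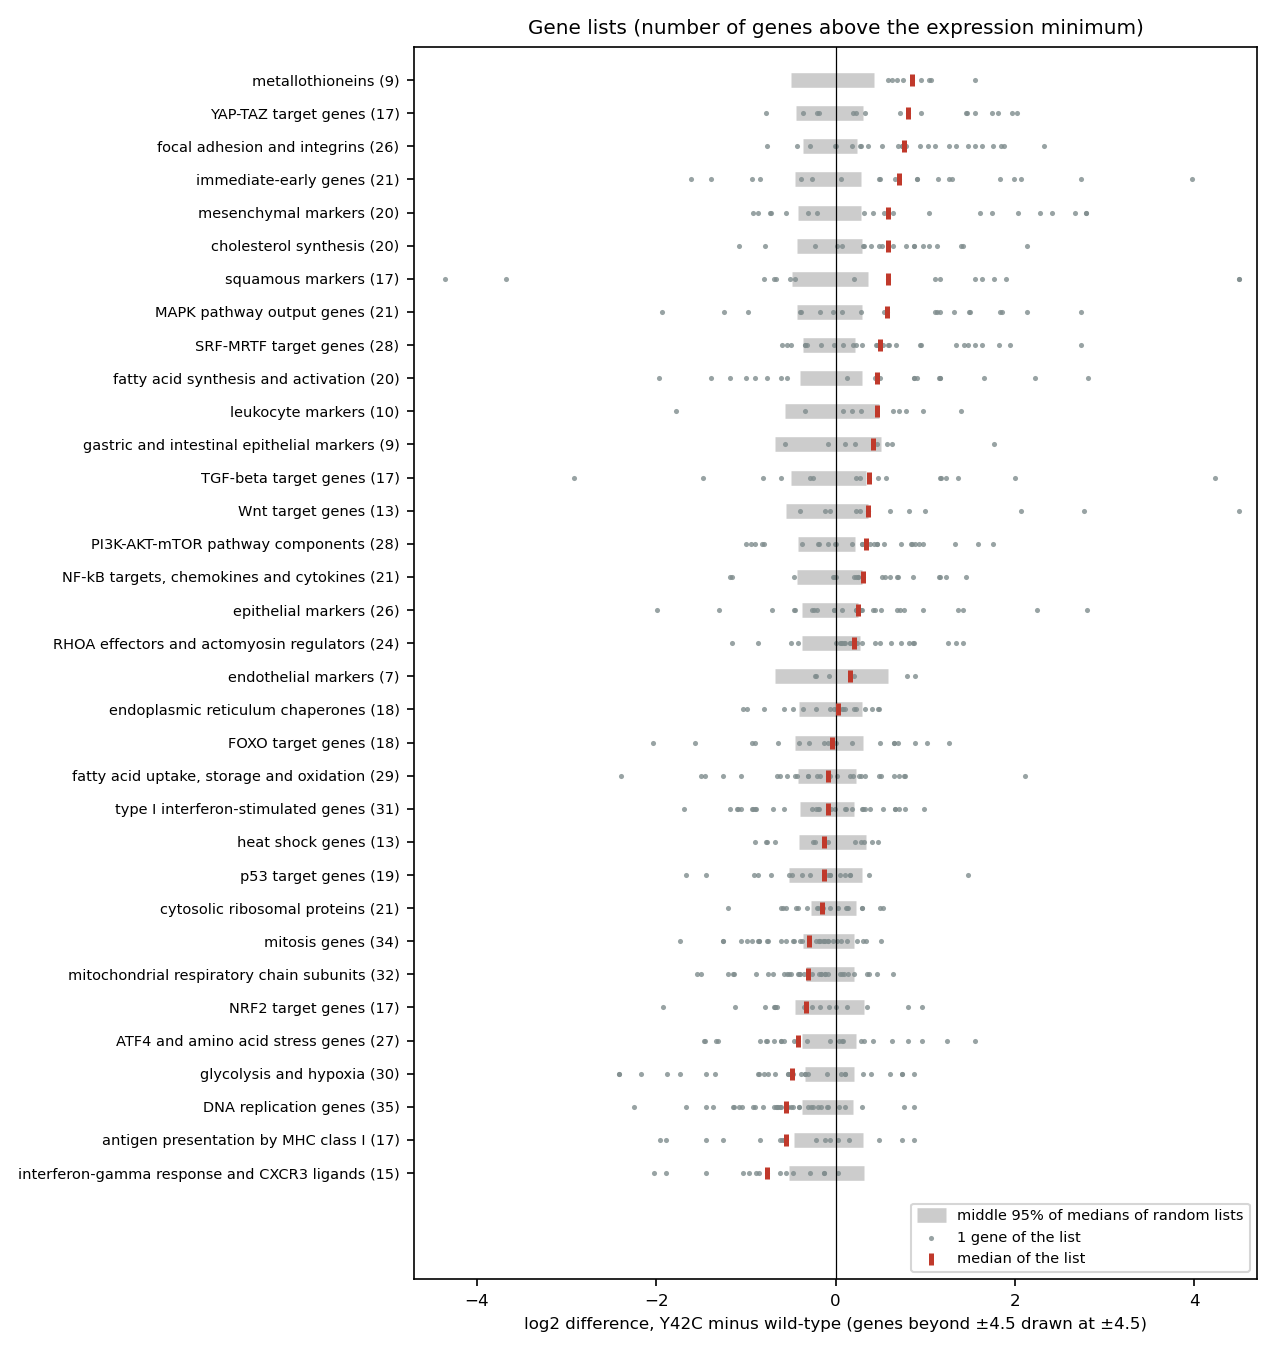
Each row is 1 of the 34 gene lists reported with its number of genes above the expression minimum; grey points are genes, the red mark is the list median, and the grey bar is the middle 95% of medians of random lists of the same size and level, all as log2 difference, Y42C minus wild-type, with genes beyond 4.5 drawn at 4.5. Of the 34 medians, 14 lie above and 5 below the bar, from 0.85 for metallothioneins to -0.77 for the interferon-gamma list.

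Genes of fatty acid synthesis differed in both directions. FASN, the fatty acid synthase, was 7.06-fold higher in the Y42C array (10.86 and 13.68). ACACA, the acetyl-CoA carboxylase that supplies it, was 4.66-fold higher (10.33 and 12.55). The desaturase genes FADS2, SCD and FADS3 were 3.14-fold, 2.25-fold and 2.23-fold higher, and SREBF1, a transcription factor of lipid synthesis, 2.22-fold. ACLY, which makes cytosolic acetyl-CoA, was 1.84-fold higher. The elongases ELOVL6 and ELOVL7 were 3.92-fold and 2.0-fold lower, the desaturase SCD5 2.62-fold, and the acyl-CoA synthetase ACSL4 2.27-fold. Of 20 members, 6 were at least 2-fold higher and 4 lower, with a median of 0.47 (-0.69 to 1.03) at percentile 99.7. The mean of 0.28 stood at percentile 96.8, and with no expression minimum the median was 0.14 at percentile 88.5.

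Cholesterol synthesis genes were more uniform. Of 20 members, 17 were higher in the Y42C array, 5 of them at least 2-fold, and STARD4, a sterol carrier, was the 1 gene at least 2-fold lower (2.11-fold). SREBF2, the main transcription factor of this pathway, was 4.41-fold and the reductase DHCR7 2.68-fold higher, and SQLE and HMGCS1 differed by 1.40 and 1.13. The median was 0.58 (0.32 to 0.93) at percentile 99.95. Genes of fatty acid uptake, storage and oxidation showed no shift as a list (29 genes, median -0.08, percentile 53.7), and their median was 0.03 once a trend on level was removed. Within it 5 genes were at least 2-fold lower, among them the lipid droplet gene PLIN2 (at least 3.0-fold) and FABP5 (2.83-fold), and 1 was higher, the transporter SLC27A2 (4.32-fold). PPARD lay at 0.77.

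Interferon-gamma response genes were lower in the Y42C array. Of 15 members above the minimum, 14 were lower, 4 of them at least 2-fold, and TAP1 was the exception at 0.03. IRF1, a transcription factor of this response, was 4.06-fold lower (8.09 and 6.07), the immunoproteasome subunits PSMB9 and PSMB8 3.71-fold and 2.71-fold, and the adhesion molecule ICAM1 2.04-fold. The median was -0.77 (-0.97 to -0.29), at percentile 0.14, and -0.44 with no expression minimum. The CXCR3 ligands CXCL9 (3.55 and 3.86), CXCL10 (4.61 and 4.04) and CXCL11 (4.47 and 4.20) were below the minimum in both arrays, so no fold is given. In the list for antigen presentation by MHC class I, 4 of 17 genes were at least 2-fold lower and 0 higher. B2M, the invariant light chain, was 3.89-fold lower and HLA-E differed by -1.26, with the 2 immunoproteasome genes making up the 4. TAPBPL (0.87) and ERAP1 (0.74) lay at the upper end. HLA genes are near-identical and may share probes. The median of -0.55 (-0.84 to 0.03) stood at percentile 0.82, at 6.98 without B2M, and inside the middle 95% under 3 other alternatives. Type I interferon-stimulated genes had a median of -0.09 over 31 genes (percentile 47.8). Of these, 5 were at least 2-fold lower, including IFIT1 (3.23-fold) and OASL (2.27-fold), and 0 were higher, with IFI6 at 0.99 and OAS1 at 0.77.

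**Figure D3:**
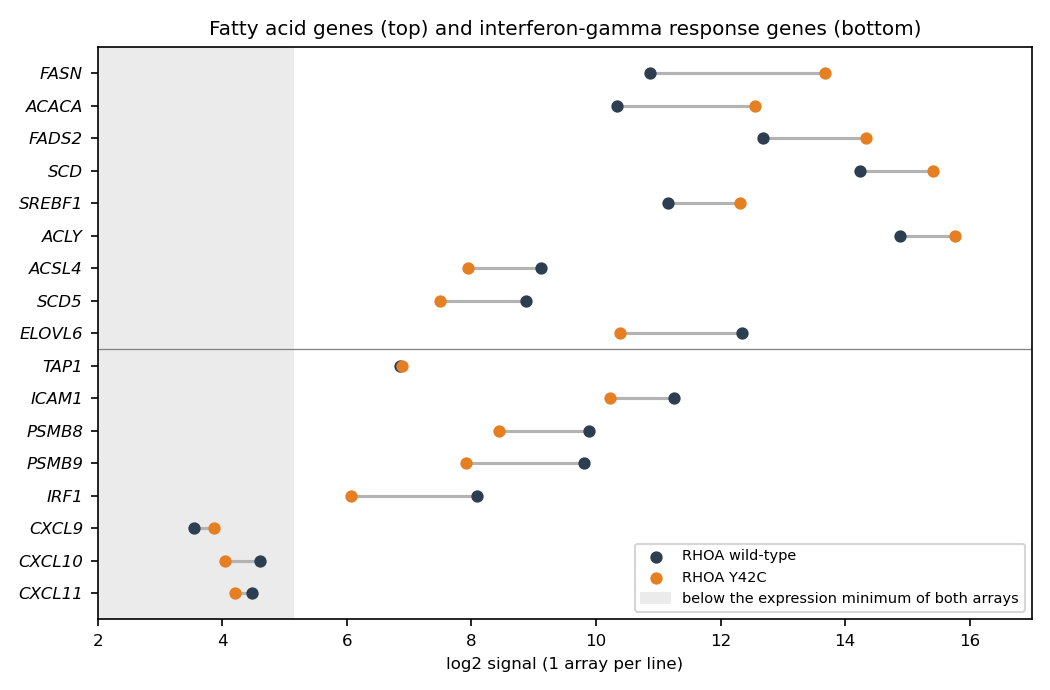
Log2 signal of 9 fatty acid genes (top) and 8 interferon-gamma response genes (bottom) in the wild-type (dark) and Y42C (orange) arrays, 1 array per line; the grey area lies below the expression minimum of both arrays. FASN goes from 10.86 to 13.68 and IRF1 from 8.09 to 6.07, while CXCL9, CXCL10 and CXCL11 lie in the grey area in both arrays.

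Components of the PI3K-AKT-mTOR pathway, which couples growth factors to lipid and protein synthesis, had 3 of 28 genes at least 2-fold higher and 1 lower. IRS1, an insulin receptor substrate, was 3.39-fold higher, the AKT phosphatase PHLPP2 3.01-fold, and the lipid phosphatase INPP5D 2.51-fold. PIK3CG was 2.0-fold lower, and RPS6KB1, an S6 kinase gene, lay at -0.94. Among the 3 higher genes, PHLPP2 and INPP5D are known to limit the pathway. The median was 0.34 (-0.05 to 0.64) at percentile 99.7. FOXO target genes, which AKT represses, had a median of -0.04 over 18 genes (percentile 56.3) and of 0.02 after centring of the arrays, with ERBB3 4.11-fold and YPEL3 2.97-fold lower and KLF6 2.39-fold and TRIB1 2.03-fold higher. ATF4 and amino acid stress genes had a median of -0.42 at percentile 1.20 over 27 genes, while the mean of -0.21 stood at 12.6 and the median with values below the minimum set to it at 3.78. DDIT4 and MTHFD2 were 2.77-fold and 2.75-fold lower, and the amino acid transporter genes SLC7A5 and SLC3A2, whose products form 1 transporter, were 2.95-fold and 2.36-fold higher.

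Outputs of growth factor signalling were higher as lists. Of 21 MAPK output genes, 10 were at least 2-fold higher and 2 lower, with a median of 0.57 (-0.03 to 1.32) at percentile 99.97, and 1.11 with the array median as minimum. SPRY2, a feedback inhibitor, was 4.41-fold higher, and DUSP5 and EPHA2 differed by 1.32 and 1.49. SPRY1 and ETV1 were 3.84-fold and 2.36-fold lower. Of 21 immediate-early genes, 8 were at least 2-fold higher and 2 lower, with a median of 0.71 (0.06 to 1.26) at percentile 99.99. Beside EGR3 and FOSL1, MYC, FOSB and EGR1 differed by 2.07, 1.99 and 1.83, and FOS by 0.06. FOSL1 also stands in the SRF-MRTF and MAPK lists, EGR1 in the MAPK list and MYC in the Wnt list. IER5 and ZFP36 were 3.05-fold and 2.62-fold lower. TGF-beta target genes had 6 of 17 at least 2-fold higher, led by PMEPA1 and SMAD7 (4.0-fold), and 2 lower, ID1 and IGFBP7 (2.79-fold). Their median of 0.37 stood at percentile 98.1, and at 97.3 without PMEPA1 and also with no minimum. Wnt target genes had a median of 0.36 over 13 genes (percentile 97.4) and a mean of 1.02 (percentile 100), and lay outside the middle 95% under 6 alternatives, with APCDD1 40.2-fold and SOX9 6.82-fold higher, 4 genes at least 2-fold higher, and NKD2 at -0.40 and NOTUM at -0.12. NF-kB targets, chemokines and cytokines had a median of 0.31 over 21 genes (percentile 98.1, 97.3 without TNFAIP3 and 97.4 with damped low values), and of 0.52 with the array median as minimum, with TNFAIP3 2.75-fold and TGFB1 2.35-fold higher, CCL28 2.27-fold lower and IL6 at least 1.69-fold lower.

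Genes of DNA replication were lower in the Y42C array. Of 35 members, 30 were lower, 8 of them at least 2-fold, and 0 were at least 2-fold higher. The helicase subunit MCM4 was 4.76-fold and the clamp loader subunit RFC4 3.18-fold lower, and POLD1 and POLA1, polymerase subunits, lay at 0.88 and 0.76. The median was -0.55 (-0.66 to -0.31), at percentile 0.07. Mitosis genes were lower in 27 of 34 cases, with 4 at least 2-fold lower, among them BIRC5 (3.32-fold) and HMMR (2.39-fold), and 0 higher. UBE2C and CCNB1 lay at 0.51 and 0.34. Their median of -0.30 (-0.61 to -0.13) stood at percentile 6.76, the mean of -0.41 at 0.30, and the median without BIRC5, -0.22, at 16.9. Glycolysis and hypoxia genes had 7 of 30 at least 2-fold lower and 0 higher, with a median of -0.49 (-0.78 to -0.21) at percentile 0.12. HK1 and PDK1 were each 5.31-fold lower, ALDOC and GPI differed by -2.17 and -1.88, and SLC2A1, the glucose transporter, and P4HA1 lay at 0.87 and 0.74. Subunits of the respiratory chain had 5 of 32 at least 2-fold lower and 0 higher, including SDHD (2.91-fold) and NDUFB5 (2.83-fold), with SDHA at 0.64 and COX6A1 at 0.46. Their median was -0.31 (-0.52 to -0.12) at percentile 3.81, the mean of -0.35 stood at 0.60, and the median without SDHD, -0.26, at 8.04.

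Among markers of cell identity, squamous genes differed in both directions. Of 17 members, 8 were at least 2-fold higher and 2 lower in the deposited values, and 5 and 2 with values below the minimum set to it. Beside SPRR1A and SPRR1B, SFN differed by 1.77 and SPRR3 was at least 1.10-fold higher, while KRT5 (-0.66) and KRT14 (0.20) did not pass 2-fold and SERPINB3 and SERPINB4 were the 2 lower genes. The median of 0.58 (-0.66 to 1.63) at percentile 99.8 had no stable sign, being -0.45 at percentile 5.44 with the array median as minimum and 0.14 at percentile 90.3 with values below the minimum set to it. Of 29 gastric and intestinal markers named here, 9 were above the minimum, with ANXA10 at least 1.30-fold higher, CDX2 at 0.63, CEACAM5 at -0.56 and GATA4 at -0.08 (median 0.42, percentile 95.6). Leukocyte markers, which a pure line should lack, had 10 of 21 genes above the minimum and a median of 0.46 at percentile 97.1, which lay outside the middle 95% under 4 alternatives. LAPTM5 was 2.64-fold higher, CD3E at least 1.41-fold higher, CD14 3.43-fold lower and TYROBP at -0.34, and with values below the minimum set to it the median was 0.25. Endothelial markers lay within the middle 95% (7 genes, median 0.16, percentile 77.3, and 0.03 with values below the minimum set to it), with VWF at 0.80, FLT1 at least 1.02-fold higher, EGFL7 at -0.23 and ERG at -0.22.

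All 9 metallothioneins, small metal-binding proteins, were higher, 3 of them at least 2-fold. MT1E was 2.93-fold and MT1G 2.08-fold higher, and the median was 0.85 (0.63 to 1.06) at percentile 99.94. These genes are near-identical and may share probes, so they are not separate observations. NRF2 target genes had 2 of 17 at least 2-fold lower, NQO1 (3.78-fold) and PGD (2.17-fold), and 0 higher, with AKR1C2 at 0.96 and ABCC3 at 0.81 (median -0.33, percentile 8.65). Of 19 p53 target genes, CDKN1A was 2.79-fold higher, RPS27L 3.18-fold and POLH 2.71-fold lower, and TP53INP1 lay at 0.37 (median -0.13, percentile 47.2). Cytosolic ribosomal proteins lay within the middle 95% (21 genes, median -0.15, percentile 14.7), with RPL14 2.30-fold lower, RPS25 at -0.61, RPS15 at 0.53 and RPL27 at 0.50. Heat shock genes (13 genes, median -0.13, percentile 29.2) had 0 members past 2-fold, from HSP90AA1 (-0.90) and HSPD1 (-0.78) to HSPH1 (0.41) and BAG3 (0.47). Endoplasmic reticulum chaperones had a median of 0.03 and a mean of -0.12 over 18 genes, so their sign depends on the summary, with CRELD2 2.04-fold lower, SDF2L1 at -0.99, CALR at 0.48 and MANF at 0.47.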

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

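The tests of shuffled differences, of the keratin-associated and olfactory receptor families and of the 2 interferon lists were chosen after the values they use had been seen. The tests of probe set pairs, gene neighbourhoods, genomic span, gene density and the MHC region were set before their results were seen.

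The comparison by gene leaves out 3739 probe sets that are unnamed here, and these stand out because many of them carry signal that is higher in the Y42C than in the wild-type array. Of 1991 above the expression minimum, 223 (11.2%) were at least 2-fold higher and 128 (6.43%) at least 2-fold lower, against 7.46% and 9.80% of the named genes. These shares were not matched on signal level, and the dimmest bin of named genes had a positive median difference (0.16) and the widest spread. The largest differences were 5.66 for probe set TC0X00008596.hg.1 (6.84 and 12.50) and 4.14 for TC0X00008826.hg.1, and -2.53 for TC0200010733.hg.1 and -2.22 for TC0400009681.hg.1.

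The first pattern is the breadth of the difference, with 881 genes at least 2-fold higher and 1157 lower between derivatives of 1 parental line. Broad copy number differences between the lines are argued against as its main source. After the median of 20 expressed neighbours on either side was subtracted, 86.8% of these genes stayed past 2-fold, which could be computed for 2036 of them. A gain or loss too short to move that median was not tested. Independent noise of single probe sets is argued against as the whole cause. Outside the middle 95% of random lists lay 20 of 36 lists, and at most 7 did in 1000 shuffles of the differences among genes of like level. The share of such noise stays open, since 2 probe sets were compared for 5 genes only (r = -0.14 across those genes). Their differences were 1.17 and -0.68 for PRKAR1A, -0.20 and 0.34 for CYP2D6, 0.66 and 1.26 for CBS, 0.46 and 0.43 for RHOU, and -0.39 and -0.05 for U2AF1. Background that depends on probe sequence, and the RHOA allele, which is confounded with the line and the array, stay open too. The 86 keratin-associated protein genes, which a gastric line is not thought to use, lay 0.12 above olfactory receptor genes (0.02 to 0.25), short of the 0.3 set for that background. Of these 86 genes, 20 were above the minimum, against 22 of 349 olfactory receptor genes. Some of them may be expressed, so the comparison cannot separate expression from background. Grouped instead by the symbol stem KRTAP, a slightly different set, 19 genes above the minimum had a median of 0.75 at percentile 100, with 5 at least 2-fold higher and 0 lower.

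The second pattern is the lower median of the DNA replication, mitosis, glycolysis and respiratory chain lists, of which the mitosis and respiratory chain medians lay inside the middle 95% of random lists. A bias tied to genomic span is argued against as the whole cause. Of the mean shift of these lists relative to all genes (-0.34), 87.1% remained after a trend on genomic span was removed (81.6% to 96.9%). This trend was shallow (r = 0.05 across genes) and spanned 0.25 between its 5th and 95th percentiles. Transcript length was not tested. A bias tied to local gene density is argued against as the main source of this shift. The trend on density was shallow (r = 0.03 across genes) and spanned 0.10, less than the shift. After its removal 103% of the shift remained (94.1% to 111%). Base composition of the transcripts was not tested, and neither was a lower growth rate or density of the culture, which may give the same pattern and which 1 culture per line cannot exclude.

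The third pattern is the lower level of interferon-gamma response and MHC class I genes. These lists share TAP1, TAP2, PSMB8, PSMB9 and PSMB10, so they are not separate observations. Loss of the MHC region is argued against, since the 137 other expressed neighbours of the 10 members on chromosome 6 had a median of -0.15 (-0.29 to -0.07), while those 10 members had a median of -0.73 and the 17 members elsewhere -0.47. A drop of interferon signalling of any kind stays open: the interferon-gamma list minus the type I list gave -0.68 (-1.07 to -0.04), but the interval covered 0 under 2 of 9 settings, with -0.26 (-0.72 to 0.23) when no expression minimum was used. The RHOA allele and a chance difference between 2 selected cell pools were not tested and stay open.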

How the results depend on the processing

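Thresholds moved the counts most: 2106 genes were higher and 2758 lower at 1.5-fold, 260 and 235 at 3-fold, and 114 and 47 when 2-fold and more than 3 times the spread from the median of like genes were required. Under the scalings, minimums, probe set choice and damping the 2-fold counts stayed within 1.5 times of 881 and 1157. The share of higher genes among them was 43.2% as deposited, 48.7% after quantile normalization and 51.9% after a level trend was removed, so the excess of lower genes depends on the scaling. With values below the minimum set to it, a choice made after seeing the data, 788 and 1074 genes passed 2-fold. Of 36 lists, 20 lay outside the middle 95% of random lists as reported, and 12 of these did so under every alternative run. The squamous list turned to -0.45 with the array median as minimum; the cause was not tested. Of the 7 main lists, all kept their sign, and 2 came inside the middle 95% under at least 1 alternative: fatty acid synthesis (0.14 with no minimum, 0.28 as a mean) and epithelial markers (0.23 without SPINT1). Of the 20 lists outside the middle 95%, 7 had a value that moved by over 1.5 times from the reported median under at least 1 alternative, and so had 13 of the 16 inside it. These alternatives include the mean of the members, which alone accounts for the ATF4 and the Wnt list. Over 1122 values of the 187 named genes under alternatives, 16 values moved by more than 0.440, the SD of olfactory receptor genes. Of the genes past 2-fold, 0 changed sign, but this was near certain in advance. The scalings shift values by far less than 2-fold, and the floor and the added constant hardly can reverse an order. No paired analysis was possible because each group has 1 sample, and for the same reason no sample could be left out. Low signal limits the smallest values: below about 5.2 on the log2 scale a gene could not be told from olfactory receptor genes.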

Other observations

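Genes were grouped into families by symbol stem, and the families and genes named here were chosen after the data were seen. The highest medians were those of the stems MMP (2.31), BMP (1.08), KLK (1.0), NPIPB (0.97), KMT (0.90), MT (0.85), KRTAP (0.75), SOX (0.69) and COL (0.62). Of 9 matrix metalloproteinase genes above the minimum, 6 were at least 2-fold higher in the Y42C array and 0 lower, with a median of 2.31 against a middle 95% of -0.62 to 0.47 for random lists. Beside MMP1 and MMP9, MMP14, a membrane-bound collagenase, was 3.94-fold higher, the stromelysins MMP3 and MMP10 at least 4.72-fold and 3.09-fold, and MMP13 at least 2.84-fold. Kallikrein-related peptidases had 6 of 12 genes at least 2-fold higher and 0 lower (median 1.0), with KLK10 4.66-fold, KLK7 3.10-fold and KLK6 2.79-fold higher. Collagens had 9 of 20 at least 2-fold higher and 1 lower (median 0.62). The basement membrane chains COL4A5 and COL4A6 were 6.36-fold and at least 4.56-fold higher, COL18A1 4.03-fold and COL12A1 3.63-fold, and COL26A1 was the 1 lower gene, at -1.08. With values below the minimum set to it, 6, 4 and 8 genes of these 3 families were at least 2-fold higher, and the medians were 1.63, 0.78 and 0.35. Metalloproteinases and kallikreins each form clusters of related genes that may share probes.

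The lowest medians were those of the stems CASP (-0.81), STARD (-0.79) and CYB (-0.77). Zinc finger genes with the stem ZNF were lower as a class, with a median of -0.36 over 397 genes, 69 of them at least 2-fold lower and 19 higher (64 and 19 with values below the minimum set to it). Large ribosomal subunit proteins of mitochondria (MRPL, 47 genes, median -0.39) and aldehyde dehydrogenases (ALDH, 16 genes, median -0.56, 5 at least 2-fold lower and 0 higher, with ALDH9A1 at -1.78) were lower too. These 3 medians kept their sign under the 3 scalings run, whose shifts are too small to reverse them. Of 212 stems with at least 8 genes, 22 lay above and 13 below the middle 95% of random lists, where 10.6 in all would be expected by chance if members were independent. Chromosome medians ran from -0.18 on chromosome 6 to 0.09 on chromosome 20.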
